A study of Homo sapiens with 6 samples.

How the data were processed

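Total RNA of A375 cells, 3 biological replicates with UBE2S knockdown and 3 control replicates, was extracted with Trizol, labelled with biotin and hybridized to Affymetrix expression arrays, per the labels' protocols. The labels call the replicates biological and name no shared day, batch or passage. The knockdown is spelled in 2 ways in the labels, which were read as UBE2S. The deposited values are on a log2 scale. Per the submitters' processing notes, limma, RMA and affy were used, with no version, role or order stated. RMA subtracts background, quantile-normalizes the arrays and summarizes probes on the log2 scale. The base of the logarithm is not stated in the file and is taken from RMA's output. In the deposited log2 table each probe set had been centred on the median of the 6 arrays (largest absolute median 4.85e-07), a step that is not described in the sources used here. It keeps differences between arrays and removes the level of each probe set, so that signal over background is unknown. Quantile normalization gives the arrays nearly the same distribution, so a change of all transcripts in 1 direction would not be seen.

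The table held 49395 probe sets, 102 of them array controls, and 0 missing values. A table of the array's annotation gave 1 gene symbol for 44988 probe sets, several for 1832 and none for 2473. Of those with 1 symbol, 44961 were matched by gene number to a gene table of assembly GRCh38.p14, and 0 symbols changed. No coordinates are given, since the array files name no genome build. The 44988 probe sets represented 18132 genes, 11734 of them with at least 2 probe sets. Replicates were compared before averaging. Pairs of arrays of 1 group differed with an SD between 0.125 and 0.144 and shared at most 140 identical values, so no array was a copy of another.

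Knockdown was compared with control by lmFit and eBayes of limma 3.58.1 in R 4.3.3, with all 6 arrays, equal weights, no block and default settings. P-values were adjusted by the Benjamini-Hochberg method over all genes or probe sets tested, and an adjusted p under 0.05 counted as changed. Standard errors are the moderated ones of this fit. All tests are two-sided. The design fixed before the data were examined took for each gene the probe set with the highest mean level and dropped genes under the 25th percentile of that mean. Centred values hold no level, so neither step could be applied. The mean of all probe sets with that 1 symbol was used instead, without a filter, both of which had been listed beforehand as alternatives. Other listed alternatives that need levels, the filter at the 50th percentile, repeated quantile normalization and a variance trend, were not run.

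In its place a coarse signal class was read from the rounding of the values, chosen after seeing the data. Values computed in single precision are multiples of a step that depends on the original size. That step placed a probe set between 8 and 16 (high), 4 and 8 (middle) or 2 and 4 (low) before centring. Classes are given per probe set, so where arrays lie on both sides of a bound the class does not hold for every array. For strongly changed probe sets the class can thus depend on the change itself. The high class held 12648 probe sets (25.7%), the middle class 27351 (55.5%) and the low class 9294 (18.9%). A probe set whose rounded values happen to be multiples of a coarser step is placed too high. Of 23 background control probe sets, 13 were in the low class, so a higher class does not show that a gene is detected. Classes served only for alternatives, for counts of low-signal genes and for a comparison within the high class in the closing section.

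Gene lists were tested with camera (competitive, preset correlation of 0.01, at least 5 measured members, adjusted over 36 lists), with camera using an estimated correlation and with fry beside it. The lists hold 1039 distinct genes, of which 956 were measured. Named genes are UBE2S, the 10 largest rises and 10 largest falls among changed genes without overlap between the groups, up to 3 changed members per direction in each list, and a fixed panel, of which 1 gene is not analysed here. In lists that were not shifted, 1 member per direction is named, a restriction made after seeing the data. The check of named genes without 1 of their probe sets, and that with their brightest signal class, with a factor of 1.5, were chosen after seeing the data. Genes named by symbol in the closing section's other observations were chosen after their values were seen.

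Alternatives were the probe set with the largest variance, centring of each array on its median, array weights, the replicate number as a block and leaving out each array in turn. Added after seeing the data were the robust variance model, the signal classes, centring on the mean of 18 hybridization or 24 poly-A spike-in probe sets, families of genes with shared leading letters and 3 lists of interferon and HLA genes, of which only counts and medians are given. The functions were tested on simulated arrays with the residual spread of the 18132 genes and 200 changed genes. At log2 changes of 0.3, 0.6, 1 and 2 they recovered 60%, 94%, 100% and 100%, with 2.75% false among the calls, and camera called the 1 shifted list and 0 of 35 others. The simulation draws genes independently and from a normal distribution, so it does not test correlated genes. It changes 200 genes, where the data called 7266. The adjustment depends on that share, so the recovery and the false share are those of the simulated setting only.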

Results

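Messenger RNA was profiled in A375, an established human melanoma cell line, after lentiviral delivery of a short hairpin RNA against UBE2S and in control A375 cells. UBE2S is a ubiquitin-conjugating enzyme that extends ubiquitin chains on the substrates of the anaphase-promoting complex (APC/C), the ligase that drives cells out of mitosis. Each group held 3 biological replicates, 1 Affymetrix array each, with 49395 probe sets per array, 102 of them array controls. The values were log2 expression centred on the median of the 6 arrays for each probe set, so they give differences between arrays and no absolute level. The 6 arrays had medians between -0.009 and 0.004 and SDs between 0.174 and 0.183 on this scale. The number of arrays limits the precision. What the control cells received is not given in the sources used here. The comparison asks which transcripts differ between UBE2S knockdown cells and control cells, and all changes are given as knockdown minus control on the log2 scale.

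UBE2S itself was lower in every knockdown array than in every control array. Its mean was -1.06 ± 0.06 (SD, n = 3) in knockdown cells and 1.03 ± 0.03 (SD, n = 3) in control cells. The difference of -2.09 (SE 0.04) left 23.5% of the control signal, a 4.25-fold reduction, with an adjusted p of 9.23e-08 in limma. The gene is read by 1 probe set, of the _s_at kind that the array names as shared, so no unshared probe set measures the size of the fall. Among all genes, 5 fell further than UBE2S.

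IFIT1 rose by 3.89 (SE 0.10), MX1 by 3.77 (SE 0.06), IFI6 by 3.05 (SE 0.04), IFITM1 by 2.45 (SE 0.05) and ISG15 by 2.20 (SE 0.08), all of them induced by interferon. The other genes among the 10 largest rises were IRF9 (2.03), a transcription factor of the interferon response, TAC1 (1.94), a precursor of the neuropeptide substance P, the viral RNA sensor RIGI (1.79), the integrin subunit ITGA7 (1.76) and the immediate-early transcription factor EGR1 (1.71). The 6 probe sets of EGR1 ranged from 0.32 to 2.96, and the only one of the high signal class gave 0.76. ESM1, a secreted proteoglycan, had the largest fall (-3.45, SE 0.04), followed by the Wnt antagonist DKK1 at -2.49 (SE 0.05), TOMM5, a subunit of the mitochondrial outer membrane import channel, at -2.15, and the collagenase MMP1 at -2.14. TNFRSF9, a receptor of the tumour necrosis factor family, fell (-2.14), as did UBE2S (-2.09), the protease MMP10 (-2.08), the signalling regulator RGS5 (-2.03), the decoy receptor TNFRSF11B (-1.95) and the hormone STC1 (-1.92). Adjusted p-values of these 20 genes lay between 1.18e-08 and 1.03e-06 in limma, and none of them overlapped between the groups.

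**Figure D1:**
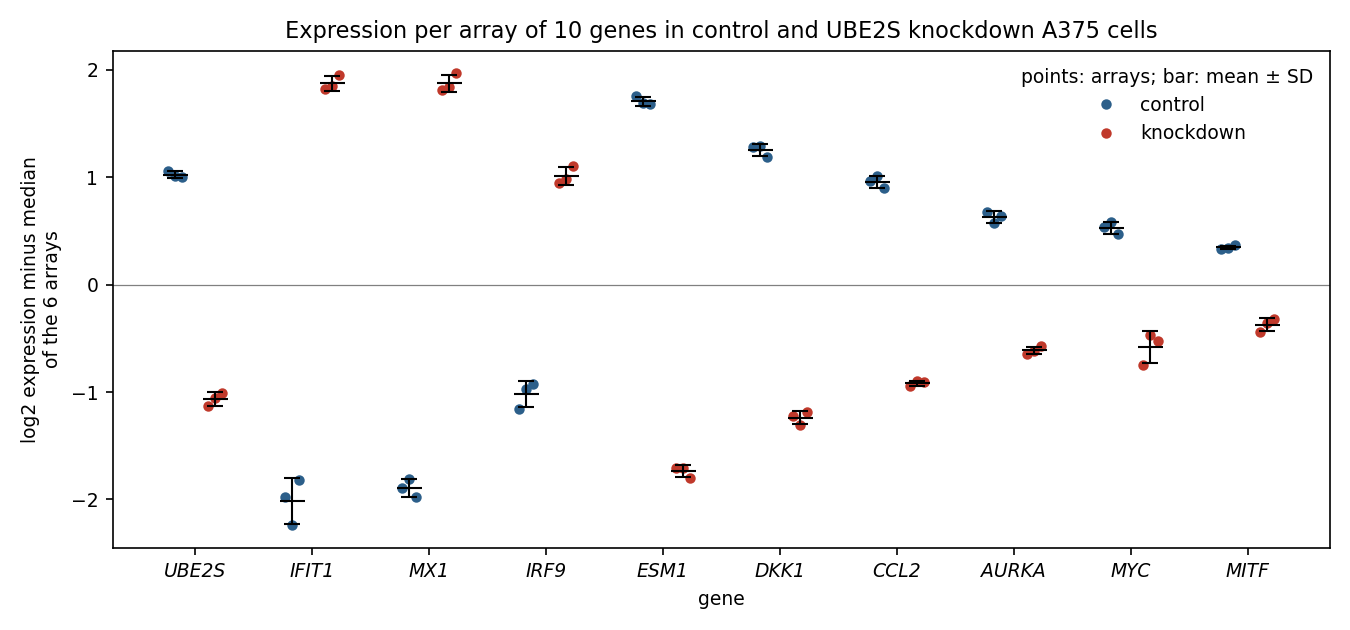
Centred log2 expression of 10 genes in each of the 3 control arrays (blue) and 3 knockdown arrays (red), with the mean and SD of each group as black bars. UBE2S lies near 1.03 in control and -1.06 in knockdown arrays, and IFIT1 runs the opposite way, from -2.01 to 1.87.

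Changes were widespread and mostly small. Of 18132 genes, 7266 changed (40.1%), 3888 upward and 3378 downward, with a median absolute log2 fold change of 0.277 among them. At least 2-fold changes were found in 193 genes, 96 higher and 97 lower. Without overlap between the groups were 9070 genes, or 50%, where 10% would come from chance. At the level of probe sets, 18189 of 49293 changed, 9628 upward and 8561 downward. When the probe set with the largest variance stood for each gene, 451 genes changed at least 2-fold. The balance of rises and falls depended on the scaling: with the arrays centred on the hybridization spike-in transcripts, which were 0.168 higher in knockdown arrays, the median change of all genes moved from -0.0038 to -0.17, and 1764 genes rose while 9196 fell. With poly-A spike-ins the split was 2486 against 6297. Changes are therefore stated relative to the array-wide level, as the deposited normalization sets it. In array control probe sets, the 3' to 5' difference of ACTB was 0.191 higher in knockdown arrays, without overlap. For GAPDH it was 0.0226 higher, with overlap. The ACTB and spike-in differences are not far below the median change of 0.277. How many of the 7266 calls reflect RNA integrity or array handling cannot be told.

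**Figure D2:**
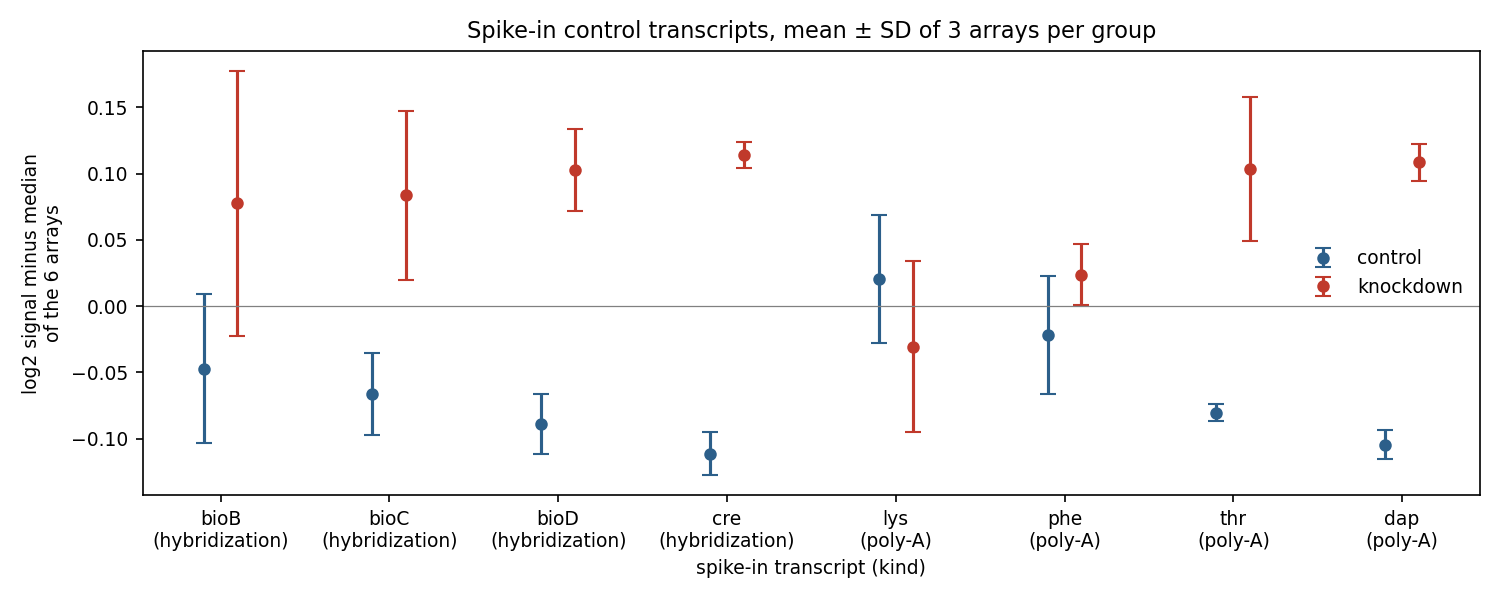
Mean and SD over 3 arrays per group of the centred log2 signal of 8 spike-in transcripts, 4 added before hybridization and 4 poly-A transcripts added to the RNA. For bioC, bioD, cre, thr and dap each knockdown array lay above each control array, with differences between 0.15 and 0.23, and lys ran the opposite way at -0.051.

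Interferon-stimulated genes rose together. Of 42 measured members, 36 rose and 0 fell, with a median change of 0.98, and the same 36 and 0 were counted adjusted over the list alone or at an unadjusted p under 0.05. Besides the genes named above, the ubiquitin-conjugating enzyme UBE2L6, which serves the ubiquitin-like protein ISG15, rose by 0.80 (SE 0.04), and the kinase EIF2AK2, a sensor of double-stranded RNA, rose by 0.73 (SE 0.04), although both had been placed in other lists. In the competitive camera test the list was shifted upward with an adjusted p of 2.00e-20, and the call held with an estimated correlation (adjusted p = 0.0286). Relative to the hybridization spike-ins 35 members rose and 5 fell, with a median of 0.81. Markers of blood cells were not shifted (2 of 14 rose and 1 fell, median 0.043, adjusted p = 0.578).

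Of the 36 gene lists fixed before the data were examined, 15 were shifted against all other genes in camera, 4 upward and 11 downward. With an estimated correlation, 2 of these calls held, those of the interferon-stimulated genes and of the ribosomal proteins.

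**Figure D3:**
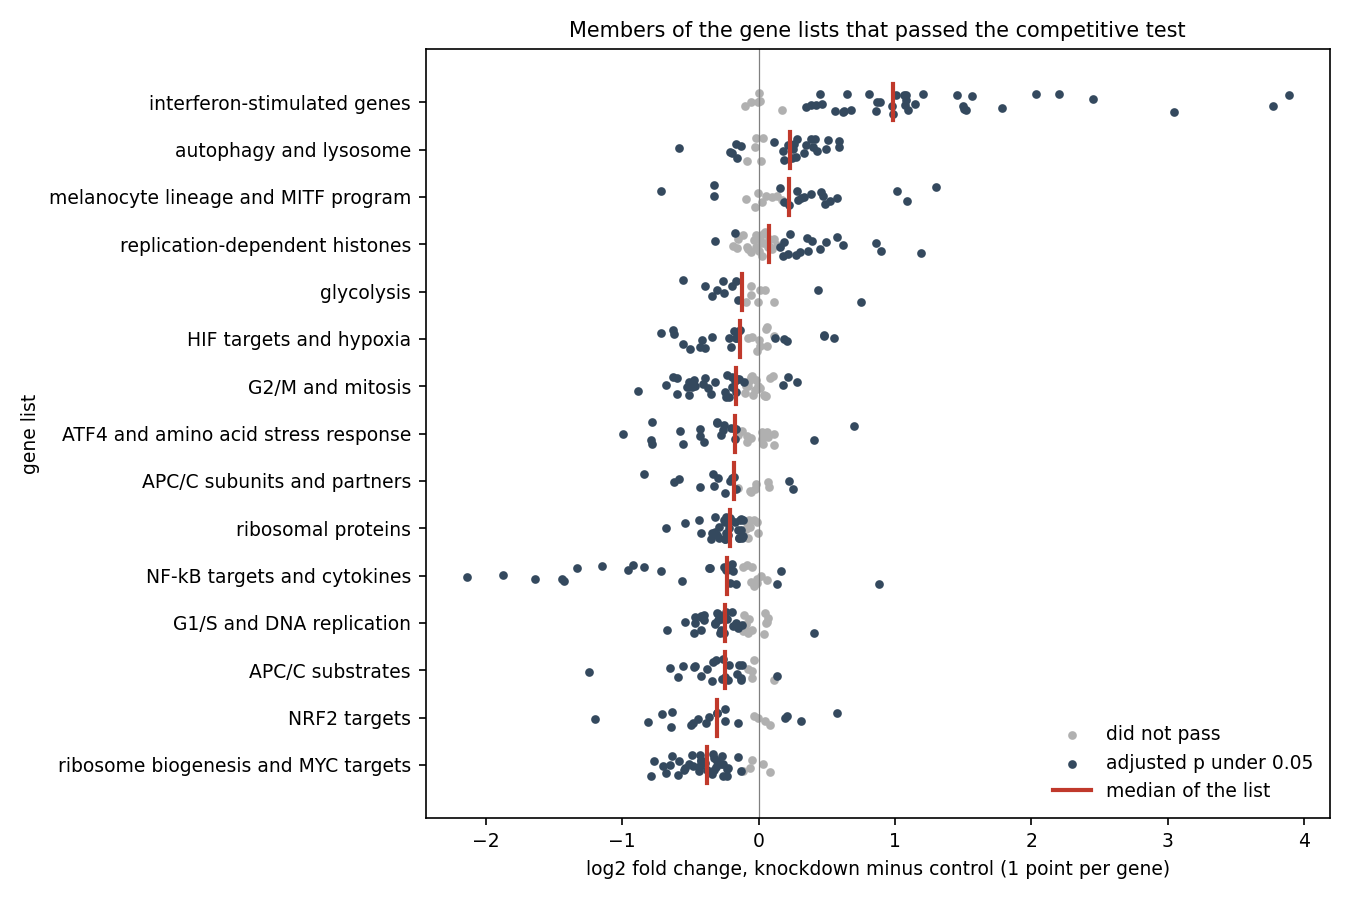
Log2 fold change of each measured member of the 15 shifted lists, with 1 point per gene, dark where the gene's adjusted p was under 0.05, and the median of each list as a red bar. Medians run from 0.98 for interferon-stimulated genes to -0.38 for ribosome biogenesis genes, and most lists hold members on both sides of 0.

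The cell division lists fell. Among 27 measured substrates of the APC/C, 21 fell and 1 rose, with a median of -0.25 and an adjusted p of 6.66e-07 in camera (adjusted p = 0.126 with an estimated correlation). Adjusted over the list alone, 21 fell and 2 rose. These are transcript values, and the substrate proteins on which the APC/C acts were not measured. The mitotic kinase AURKA fell (-1.24, SE 0.04), as did the cohesion protector CDCA5 (-0.65) and the cyclin CCNA2 (-0.59). BIRC5, a subunit of the chromosomal passenger complex, rose by 0.14 (SE 0.04), a rise that turned to -0.030 with hybridization spike-in centring. In the list of APC/C subunits and partners, 12 of 21 fell and 2 rose, as they did adjusted over the list alone, with a median of -0.18 (adjusted p = 0.00600, and adjusted p = 0.2996 with an estimated correlation). The call was lost with probe sets of the high signal class only. UBE2C, the enzyme that starts the chains UBE2S extends, fell (-0.84, SE 0.04), as did the APC/C inhibitor FBXO5 (-0.62) and the subunit ANAPC15 (-0.58). The subunits ANAPC5 and ANAPC13 rose by 0.25 and 0.22, and neither passed the test with hybridization spike-in centring (0.085 and 0.052). The coactivator CDC20 fell (-0.43, SE 0.04), as did the subunit ANAPC4 (-0.20), whereas FZR1 (-0.025, SE 0.05), ANAPC2 (-0.022, SE 0.06) and ANAPC11 (0.069, SE 0.03) did not pass the test.

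Genes of G1/S and DNA replication fell in 27 of 40 cases and rose in 1, with a median of -0.25 and an adjusted p of 2.12e-07 (adjusted p = 0.134 with an estimated correlation). Adjusted over the list alone, 29 fell and 1 rose. The replicative helicase subunit MCM4 fell (-0.67, SE 0.04), and the helicase partners GINS2 and GINS3 fell (-0.54 and -0.48), while another subunit, MCM6, rose by 0.41 (SE 0.06). Of 46 genes of G2/M and mitosis, 27 fell and 3 rose (28 and 4 adjusted over the list alone), with a median of -0.17 and an adjusted p of 1.45e-05 (adjusted p = 0.2996 with an estimated correlation). The kinesin KIF20A fell (-0.88, SE 0.07), as did the condensin subunit NCAPG (-0.68) and the spindle protein DLGAP5 (-0.63). Topoisomerase TOP2A rose by 0.28, the microtubule polymerase CKAP5 by 0.22 and the kinase PBK by 0.18, and none of the 3 passed the test with hybridization spike-in centring (0.11, 0.049 and 0.010). From the panel fixed in advance, the proliferation marker MKI67 fell (-0.60, SE 0.04), as did the kinase PLK1 (-0.55) and cyclin CCNB1 (-0.47), and cyclin CCND1 rose by 0.41 (SE 0.03). CDKN1A, an inhibitor of cyclin-dependent kinases, stood at -0.11 (SE 0.04) with an adjusted p of 0.0489, a call lost without 5 of the 6 arrays in turn. CCNE1 (0.058) and CDKN1B (0.086) did not pass the test.

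Genes of the ribosome fell. Of 39 ribosomal proteins 31 fell and 0 rose, with a median of -0.21, an adjusted p of 1.05e-09 in camera and an adjusted p of 0.0286 with an estimated correlation. Adjusted over the list alone, and at an unadjusted p under 0.05, 32 fell and 0 rose. RPS2 fell (-0.68, SE 0.05), as did RPL5 (-0.54) and RPS20 (-0.44). For RPS2 the probe sets gave -1.12 and -0.23, and for RPS20 they gave -1.12, -0.17 and -0.017, so that 1 probe set of a lower signal class carries much of each value. Of 41 genes of ribosome biogenesis and MYC targets, 36 fell and 0 rose, with a median of -0.38 and an adjusted p of 5.45e-15 (adjusted p = 0.154 with an estimated correlation). The list-alone adjustment gave 37 falls and 0 rises, as did an unadjusted p under 0.05. LYAR, a nucleolar protein, fell (-0.79, SE 0.03), as did the small-subunit processome component UTP20 (-0.77) and the growth regulator PA2G4 (-0.70). The transcription factor MYC, which drives ribosome production, fell (-1.11, SE 0.07). In the array's 3' to 5' control probe sets for ACTB, the difference was 0.191 higher in knockdown arrays without overlap, and for GAPDH it was 0.0226 higher with overlap.

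In the mixed list of NF-kB targets and cytokines, 21 of 33 fell and 3 rose, as they did adjusted over the list alone, with a median of -0.23 and an adjusted p of 1.57e-07 (adjusted p = 0.134 with an estimated correlation). MMP1, named above, led the falls, with the monocyte chemokine CCL2 at -1.88 (SE 0.04) and the neutrophil chemokine CXCL3 at -1.64 (SE 0.04). The cytokine IL11 rose by 0.89 (SE 0.04). TRAF1, an adaptor of tumour necrosis factor receptors, rose by 0.16 and the cytokine LIF by 0.14, and both turned slightly negative with hybridization spike-in centring (-0.0059 and -0.031).

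Of 32 genes of the ATF4 and amino acid stress response 18 fell and 2 rose (19 and 4 adjusted over the list alone), with a median of -0.17 and an adjusted p of 1.17e-04 (adjusted p = 0.267 with an estimated correlation). The amino acid transporters SLC7A5 and SLC7A1 fell (-0.99 and -0.78), and the mitochondrial serine enzyme SHMT2 fell (-0.79), each with an SE of 0.04. DDIT3, a transcription factor induced in prolonged endoplasmic reticulum stress, rose by 0.70 (SE 0.05), and CTH, an enzyme of cysteine synthesis, by 0.41. Among 23 NRF2 targets, the genes of the antioxidant response, 15 fell and 4 rose, as they did adjusted over the list alone, with a median of -0.31 and an adjusted p of 9.09e-04 (adjusted p = 0.231 with an estimated correlation). The aldo-keto reductases AKR1C2 and AKR1C1 fell (-1.20 and -0.81), as did the pentose phosphate enzyme TKT (-0.71), while the peroxiredoxin reductase SRXN1 rose by 0.57, TALDO1 by 0.31 and EPHX1 by 0.21, of which TALDO1 (0.15) and EPHX1 (0.038) did not pass the test with hybridization spike-in centring. The call of the NRF2 list was lost with probe sets of the high signal class only.

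Of 31 HIF targets and hypoxia genes 16 fell and 6 rose, as they did adjusted over the list alone, with a median of -0.14 and an adjusted p of 0.0431 (adjusted p = 0.2996 with an estimated correlation). PDK1, a brake on pyruvate oxidation, fell (-0.72, SE 0.06), as did the collagen hydroxylase subunit P4HA1 (-0.63) and the mTOR inhibitor DDIT4 (-0.62). BHLHE40 rose by 0.55, ANGPTL4 by 0.48 and PFKFB4 by 0.48. HIF1A, the oxygen-regulated transcription factor, fell (-0.45, SE 0.03), as did VHL (-0.17, SE 0.04), the ligase subunit that marks it for destruction. Of 18 glycolysis genes 9 fell and 2 rose (10 and 3 adjusted over the list alone), with a median of -0.12 and an adjusted p of 0.0466 (adjusted p = 0.323 with an estimated correlation). PGK1 fell (-0.56, SE 0.03), as did ENO1 (-0.39) and ALDOC (-0.34), and ENO2 and PFKP rose by 0.75 and 0.44. The calls of both lists were lost under either spike-in centring, with the replicate block, without knockdown replicate 1 and without control replicate 2. Glycolysis also lost its call without knockdown replicate 2, without control replicate 1, with the largest-variance probe set and without the low signal class, and HIF targets lost theirs with the high signal class only.

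Genes of the melanocyte lineage and MITF program rose in 16 of 27 cases and fell in 3 (18 and 3 adjusted over the list alone), with a median of 0.22 and an adjusted p of 5.35e-04 (adjusted p = 0.174 with an estimated correlation). RLBP1, a retinoid-binding protein, rose by 1.30 (SE 0.07), the calcium-binding melanoma marker S100B by 1.09 (SE 0.04) and RAB27A, a GTPase of melanosome transport, by 1.02 (SE 0.05). MITF, the transcription factor after which the program is named, fell (-0.72, SE 0.04), as did the melanosome genes GPR143 (-0.33) and RAB38 (-0.33). SOX10, an upstream factor of the lineage, stood at 0.13 (SE 0.05) and did not pass the test with an adjusted p of 0.0703. Of 30 genes of autophagy and lysosome 19 rose and 6 fell, as they did adjusted over the list alone, with a median of 0.23 and an adjusted p of 0.00461 (adjusted p = 0.323 with an estimated correlation). GABARAP, a coat protein of autophagosomes, rose by 0.59 (SE 0.04), the lysosomal protease CTSD by 0.59 and the sialidase NEU1 by 0.51. The autophagy receptor SQSTM1 fell (-0.59, SE 0.03), as did the lysosomal galactosidase GLA (-0.21) and the proton pump subunit ATP6V0D1 (-0.19). Relative to the hybridization spike-ins the 2 medians were 0.056 and 0.060, with 10 rises and 6 falls among melanocyte and MITF genes and 10 rises and 11 falls among autophagy and lysosome genes.

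Replication-dependent histone genes rose in 17 of 43 cases and fell in 2 (17 and 3 adjusted over the list alone), with a median of 0.077 that turned to -0.090 and -0.021 with hybridization and poly-A spike-in centring. With hybridization spike-in centring 9 rose and 12 fell. The list was shifted upward against other genes with an adjusted p of 0.0210 (adjusted p = 0.172 with an estimated correlation). The linker histone H1-2 rose by 1.19 (SE 0.05), H2AC8 by 0.89 and H2AC11 by 0.86, and H2BC6 and H4C13 fell (-0.32 and -0.17). Of the 43 genes, 15 had no probe set above the lowest signal class.

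The other 16 lists of pathways and programs were not shifted, although 4 of them were called under some alternatives. ERK pathway output was called under both spike-in centrings, oxidative phosphorylation under both and with the largest-variance probe set, p53 targets with that probe set and cholesterol synthesis without control replicate 3. Of 32 p53 targets 6 rose and 11 fell (median -0.063, adjusted p = 0.136). RRM2B, a ribonucleotide reductase subunit, rose by 0.51 and the nuclease AEN fell (-0.69), while MDM2, the main ligase of p53, stood at -0.022 (SE 0.04) and did not pass the test. Of 29 apoptosis regulators 7 rose and 8 fell (adjusted p = 0.828), with the cell death promoter BAD up by 0.78 and the survival gene BCL2A1 at -0.51. In the unfolded protein response of the endoplasmic reticulum 6 of 26 rose and 10 fell (adjusted p = 0.252), with the cochaperone DNAJB9 up by 0.68 and the translocon subunit SEC61B at -0.83. Among 19 heat shock proteins 7 rose and 3 fell (adjusted p = 0.239), with HSPA1B up by 0.85 and CHORDC1 at -0.64. With hybridization spike-in centring 4 rose and 9 fell, and the median turned from 0.062 to -0.11. Of 31 proteasome genes 6 rose and 8 fell (adjusted p = 0.528), with PSMB6 up by 0.25 (0.083 and not passing the test with hybridization spike-in centring) and PSMA1 at -0.59, where 1 of its probe sets gave -1.20 and the other 0.027. Of 25 ubiquitin-conjugating enzymes other than UBE2S, 9 rose and 8 fell (adjusted p = 0.858), with UBE2L6 and UBE2C, both named above, at the ends. With hybridization spike-in centring 6 rose and 14 fell. Rises and falls under that centring were 4 and 24 for p53 targets and 2 and 18 for apoptosis regulators. They were 2 and 15 for the unfolded protein response and 0 and 18 for proteasome genes.

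In homologous recombination repair 2 of 25 rose and 5 fell (adjusted p = 0.652), with the kinase ATM up by 0.30 and the nuclease EXO1 at -0.32. Of 19 genes of cholesterol synthesis and SREBP2 targets 3 rose and 10 fell (adjusted p = 0.0691), with SC5D up by 0.47 and INSIG1 at -0.72. Of 43 genes of oxidative phosphorylation 5 rose and 16 fell (adjusted p = 0.0905), with NDUFC1 up by 0.19 (0.023 and not passing the test with hybridization spike-in centring) and SDHC at -0.86. Of 18 genes of the microRNA and RNA interference machinery 7 rose and 4 fell (adjusted p = 0.320), with EIF2AK2, named above, highest and TARBP2 lowest at -0.26, where 1 of its probe sets gave -0.70 and the other 0.17. With hybridization spike-in centring 4 rose and 8 fell, and the median turned from 0.058 to -0.11. Rises and falls under that centring were 1 and 18 for homologous recombination, 1 and 12 for cholesterol synthesis and 0 and 30 for oxidative phosphorylation.

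Outputs of the ERK pathway, the growth signal that melanoma cells often depend on, moved both ways, with 14 of 27 rising and 7 falling (median 0.13, adjusted p = 0.136). With hybridization spike-in centring 9 rose and 12 fell, and the median turned to -0.036. EGR1 rose and MYC fell, with the values given above. Of 23 Wnt and beta-catenin targets 3 rose and 5 fell (adjusted p = 0.371), with CCND1 and DKK1 at the ends, and CTNNB1, the gene of beta-catenin, rose by 0.13 (SE 0.04, adjusted p = 0.0235), a value of -0.039 with hybridization spike-in centring. Of 22 TGF-beta targets 5 rose and 7 fell (adjusted p = 0.208), with the matrix protein TGFBI up by 0.55 and fibronectin, FN1, at -1.18 (SE 0.03). The AXL and invasive melanoma program held 9 rises and 12 falls among 28 genes (adjusted p = 0.560). The receptor kinase AXL rose by 0.87 (SE 0.04) and the matricellular gene CCN1 fell (-0.9997, SE 0.05). Of 38 mesenchymal and matrix genes 12 rose and 11 fell (adjusted p = 0.692), led by THBS2 at 1.36 (SE 0.07) and MMP1, and with hybridization spike-in centring 8 rose and 18 fell. Of 22 epithelial genes 2 rose and 5 fell (adjusted p = 0.0937), with the keratin KRT7 at -1.08 (SE 0.05) and the junction gene TJP1 up by 0.36, where 1 of its probe sets gave 0.74 and the other -0.013. Rises and falls with hybridization spike-in centring were 1 and 13 for Wnt targets and 4 and 14 for TGF-beta targets. They were 6 and 15 for the AXL program and 1 and 12 for epithelial genes. The cadherins CDH1 (-0.070) and CDH2 (-0.072) did not pass the test, and the filament gene VIM fell (-0.14). The reference genes GAPDH (-0.058) and ACTB (-0.057) did not pass the test either, and both passed it at -0.23 and -0.22 with hybridization spike-in centring.

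Of 88 changed named genes with several probe sets, 15 had a mean change that shrank by a factor over 1.5 or reversed when 1 probe set was left out. Besides RPS2 and RPS20, the change became -0.68 for AKR1C2, -0.46 for TKT, -0.40 for NCAPG, -0.28 for CDC20, -0.13 for PRRX1, -0.080 for GLA, -0.038 for BCL2A1, 0.051 for CKAP5, 0.21 for HBB and 0.20 for LIN28B. It reversed for PSMA1, TARBP2 and TJP1, to the values of the other probe set given above. In the check by brightest signal class that follows, the class of a strongly changed probe set can depend on the change itself. With only the probe sets of the brightest signal class of each gene, 14 changed named genes differed by a factor over 1.5, 8 with a smaller or reversed value (EGR1, NCAPG, TJP1, TKT, RPS2, RPS20, HBB and LIN28B) and 6 with a larger one (BCL2A1, SLC7A1, PSMA1, AKR1C2, GABARAP and PRRX1).

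Marker lists of other cell types, which check for RNA of other cells, were not shifted. Besides the blood cell markers, where HBB was 0.41 higher and FCER1G stood at -0.14, 1 of 13 keratinocyte markers rose and 1 fell (KRT10 0.22 and KRT14 -0.46, adjusted p = 0.918), and KRT10 did not pass the test with hybridization spike-in centring (0.053). Of 17 fibroblast markers 2 rose and 3 fell (LUM 0.93 and PRRX1 -0.33, adjusted p = 0.828), and of 13 endothelial markers 2 rose and 1 fell (EGFL7 0.32 and ROBO4 -0.72, adjusted p = 0.858). Of 11 markers of the kidney cells used to package lentivirus 3 rose and 2 fell (LIN28B 0.57 and NEFL -0.74, adjusted p = 0.858). With hybridization spike-in centring the counts were 2 rises and 4 falls for blood cell, 1 and 7 for endothelial and 1 and 4 for kidney markers. They were 0 and 7 for keratinocyte and 1 and 11 for fibroblast markers. In the lists that were not shifted, adjustment over the list alone gave 11 falls in the unfolded protein response, 11 in cholesterol synthesis and 9 among TGF-beta targets, 13 rises among mesenchymal genes, 10 in the AXL program and 2 among Wnt targets, 0 falls among blood cell markers, and otherwise the same counts. The median and the mean differed in sign for the mesenchymal (0.055 and -0.031), apoptosis (-0.012 and 0.0096), fibroblast (-0.023 and 0.028), endothelial (0.0078 and -0.0038) and kidney lists (0.016 and -0.021), where camera's direction followed the median.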

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

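The tests of blood cell markers, of random bright lists, of 3' to 5' signal and of probe sets shared with pseudogenes were chosen after the results they bear on were seen, as was centring on spike-ins.

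Array control transcripts, which come from bacteria or phage and are added in fixed amounts, take no part in the comparison of genes and yet separated the groups. Each of the 3 knockdown arrays lay above each control array for bioC (difference 0.150, log2), bioD (0.192), cre (0.225), thr (0.184) and dap (0.213). For bioB (0.125), phe (0.046) and lys (-0.051) the groups overlapped. The mean over hybridization spike-ins differed by 0.168 and that over poly-A spike-ins by 0.098. Hybridization spike-ins are added after labelling, so their difference does not measure the share of mRNA in the RNA. The poly-A spike-ins, added to the RNA, ran from -0.051 to 0.213. Whether their added amounts or the share of cellular mRNA differed cannot be told. Values centred on spike-ins therefore show how results depend on scaling and are not a measure of absolute change. An exact permutation test of 3 arrays against 3 cannot give less than 0.1, which is what the separated transcripts gave.

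With 3 arrays per group there are 10 splits, too few for a share under 0.05. The real split gave 7266 changed genes, 193 genes changed at least 2-fold and 18189 changed probe sets, and 1 of the 10 splits, the real one, gave as many in each case. The highest of the other splits was 0 in all 3 counts in limma, with up to 381, 0 and 1027 at an unadjusted p under 0.05. For gene lists 2 of the 10 splits gave as many as the real one: it shifted 15 lists, and the highest of the others also shifted 15, of which 12 were shifted the same way in the real split. Each other split keeps part of the real difference, since its groups hold knockdown and control arrays in a ratio of 2 to 1. That mixing also puts the real difference into the spread within the groups, which lowers the counts of genes and probe sets. The counts of 0 in the other splits therefore say nothing about chance.

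Interferon-stimulated genes rose in 36 of 42 cases. RNA of blood cells would raise their markers too, but the median change of 14 blood cell markers was 0.0433 (95% bootstrap interval -0.0267 to 0.0545), below the bound of 0.2. A median over markers of several cell types cannot exclude RNA of a single type. Of the 14 markers 2 rose, among them HBB by 0.41, and 4 had no probe set above the lowest signal class. A higher class does not show detection, since 13 of 23 background control probe sets were in the lowest class. How many of the 14 markers were detected is therefore unknown. A shift of all values is argued against by the list's median of 0.814 relative to the hybridization spike-ins. The range for 2 standard errors of this median either way was 0.457 to 1.17. That range treats the members as independent and leaves out the spread of the spike-ins between arrays. An effect of less UBE2S, and an effect of the hairpin vector or its sequence, such as sensing of double-stranded RNA, cannot be told apart, because the labels hold 1 knockdown group and name no second hairpin or rescue. Both stay open, and the biological one is a hypothesis.

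Ribosomal protein and ribosome biogenesis genes fell, and with an estimated correlation the call of the first holds (adjusted p = 0.0286) and that of the second is lost (adjusted p = 0.154). The broader families with the leading letters RPL and RPS lost their camera calls with an estimated correlation (adjusted p = 0.490 and 0.797 over 244 families). A shift common to the whole high signal class is argued against by the median of -0.0011 of its 11409 other probe sets. In that class the ribosomal protein probe sets had a median of -0.145 and the biogenesis probe sets one of -0.385. Of 10000 random lists drawn from the others, 0.01% had a median as low as the first and 0% as low as the second. The random lists were not matched for brightness within the class, so a shift of its brightest probe sets was not tested. They also draw probe sets independently, whereas several ribosomal probe sets can read 1 gene, so these shares may be too small. The fall of ribosomal protein probe sets was not confined to those named as shared. The 37 others had a median of -0.159 (95% bootstrap interval -0.2504 to -0.0804), against -0.169 for the 70 named as shared. The bound of -0.05 for this interval was set after its value was seen. Of the 37, 16 fell, against 43 of the 70. Whether the array's naming covers processed pseudogenes is not given here, so cross-hybridization to them is not decided. RNA integrity stays open and cannot be told apart from the groups, since the 3' minus 5' difference was 0.0226 for GAPDH with overlapping groups and 0.191 for ACTB with separated groups. A biological cause is a hypothesis that no value here tests, since neither growth nor division was measured, and counts of cells over time with a second hairpin would be needed.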

How the results depend on the processing

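UBE2S kept its direction and call in all 16 alternatives, between -2.26 and -2.05. The mean-level filters, the highest-mean probe set, repeated quantile normalization and the variance trend were not run, since the centred values hold no level, and signal over background limits which genes can be judged: 56.7% of high-class, 37.2% of middle-class and 8.92% of low-class probe sets changed. Alternatives by signal class, robust variance and spike-ins were added after seeing the data. Of 147 other named genes, 118 kept direction and call in every alternative that tested them and 137 without each array in turn, where 6331 to 6637 genes changed. The replicate numbers do not pair the arrays (same-number deviations correlate at -0.019, -0.014 and -0.062), and with the replicate block 6684 genes changed, 6511 of them also in the unblocked fit. HIF targets and glycolysis lost their calls there.

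Genes changed were 4445 with the high signal class only, where 6486 genes were tested, and 10960 with centring on hybridization spike-ins. Genes changed at least 2-fold were 127 with the high signal class only and 451 with the largest-variance probe set, since it picks the most variable probe set. Probe sets changed were 8746 with the high signal class only. Gene lists shifted were 2 with an estimated correlation, 29 in fry for one direction and 36 for either, which tests members against no change. Under hybridization spike-in centring, which lowers every gene by 0.168, BIRC5 turned to -0.030, TRAF1 to -0.0059, LIF to -0.031, CTNNB1 to -0.039, SOX10 to -0.034, ANAPC11 to -0.099, CCNE1 to -0.11 and CDKN1B to -0.082, and under poly-A centring the last 3 to -0.029, -0.040 and -0.012. With the direction kept, 10 named genes lost their call and 7 gained one under hybridization centring, against 7 and 5 under poly-A centring. With the high class only and with each gene's brightest class alike, TJP1 turned to -0.013 and MDM2 to 0.063, because other probe sets dropped out. With the largest-variance probe set FZR1 turned to 0.0045 and ANAPC2 to 0.17, neither called. Leaving out 1 array gave -0.076 to 0.015 for FZR1 and -0.057 to 0.035 for ANAPC2.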

Other observations

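All tests in this part were chosen after the data were seen, except the prediction on cross-hybridizing probe sets, and the genes were named after their values were seen. The HLA family of 21 genes, 4 risen and 11 fallen, was not called in camera over 244 families (adjusted p = 0.0723, and adjusted p = 0.797 with an estimated correlation). Its 2 classes were set apart after these values were seen, so no test of either class is given. Of 14 HLA class II genes with their partners CD74 and CIITA, 13 fell and 0 rose (14 and 0 at an unadjusted p under 0.05 in limma), with a median of -0.35. HLA-DPA1 fell (-0.81), as did HLA-DRA (-0.40), the invariant chain CD74 (-0.35) and the coactivator of class II transcription CIITA (-0.35). Of 7 HLA class I genes with B2M and TAP1, 5 rose and 0 fell (5 and 1 unadjusted), with a median of 0.42. HLA-C rose by 0.68, HLA-B by 0.63, TAP1 by 0.65 and B2M by 0.42. HLA-B, HLA-C, TAP1 and B2M are also in the list of interferon-stimulated genes, so their rises repeat part of that result. Both medians kept their sign with spike-in centring, at -0.52 and 0.25 for the hybridization spike-ins.

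The interferon genes themselves did not rise with their targets. Of 17 measured, 0 rose and 1 fell (1 and 2 at an unadjusted p under 0.05 in limma), the fall being that of IFNE at -0.53, and 15 had no probe set above the lowest signal class, a class in which few probe sets changed. IFNB1 stood at 0.13 (adjusted p = 0.127) and IFNL1 at -0.043 (adjusted p = 0.679). Among sensors of viral nucleic acid, IFIH1 rose by 0.46 and DHX58 by 0.61 beside RIGI, whereas CGAS (0.034) and STING1 (-0.033) did not pass the test. The RNA-editing enzyme ADAR rose by 0.66.

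Of 244 families of genes with shared leading letters, 14 were shifted in camera, 3 upward and 11 downward, and 0 with an estimated correlation (lowest adjusted p = 0.490). That lowest value belonged to the letters RPL, where 34 of 51 genes fell and 2 rose, with RPL27A lowest at -1.76. The letters RPS, which also take in genes such as RPS6KA3, held 20 falls and 5 rises among 38 genes. Beta protocadherins, adhesion proteins encoded in 1 cluster, rose in 15 of 18 cases and fell in 0, with a median of 0.27, led by PCDHB15 at 0.99. Mitochondrial ribosomal proteins of the large subunit fell in 23 of 48 cases and rose in 5 (median -0.13), subunits of the mitochondrial inner membrane translocase fell in 9 of 14 and rose in 1 (median -0.20), with TIMM17A at -0.94, and splicing factors of the SRSF family fell in 8 of 12 and rose in 0 (median -0.23), with SRSF1 at -0.57. The last 4 families are examples, and their medians kept their sign with both spike-in centrings. Semaphorins, called upward with 10 of 20 risen and 1 fallen, did not: their median of 0.15 turned to -0.017 with hybridization spike-ins.

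Probe sets of 1 gene can disagree. Among 14899 pairs of changed probe sets of the same gene, 892 (5.99%) went in opposite directions, in 410 genes. Cross-hybridization may explain such pairs if they often hold a probe set that the array names as shared. Such a probe set was in 49.3% of opposite pairs and in 61.3% of all these pairs, a ratio of 0.804. Probe sets of 1 gene that read the same sequence agree and can raise the second share, so the ratio does not decide the question. Different transcript ends of 1 gene remain a hypothesis that was not tested.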
